A study of Mus musculus with 186 samples.

How the data were processed

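The series holds 186 samples of mouse RNA, of which 1 was assigned to no group. Per the labels, cortical neurons were dissected from CD1 embryos, cultured, and treated with DMSO, U0126 or cycloheximide, and visual cortex was taken from adult male mice given corn oil or SL327. RNA was extracted on columns with a DNase step, made into stranded total RNA libraries, and for the captured libraries hybridised to RNA baits, per the labels' protocols. STAR, SAMtools and bedtools and the build mm9 are named in the submitters' processing notes, with no versions.

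The file headers name no unit, so the units were worked out from the deposited values. The captured tables were deposited as a signal in which every column holds whole multiples of 1 step, taken as 1 read (tolerance 0.05 reads, 100% of values whole in every table). In the culture gene capture the deposited signal is reads divided, per sample, by the geometric mean of 47 genes of the panel. This first form held in 0 of 66 columns (tolerance 1e-06), and after 0.01 read was added to each gene it held in 66 of 66, so the offset was inferred from the values after the plain form had failed. In the visual cortex tables the arithmetic mean of the same 47 genes was 1 in 39 of 39 deposited columns. The factor behind the captured enhancer signal is not given in the sources used here. The intron table of total RNA was deposited in RPM, worked out from its columns, which sum to between 963706 and 966590. The enhancer table of total RNA was read as RPM too, but the total behind it is not given in the sources used here and differs from that of the introns. For unstimulated vehicle replicate 1 a value of 1 stood for 27.2 reads in the enhancer table and 16.1 in the intron table. Each table was normalised by itself, and levels are compared within an experiment.

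Some deposited columns were left out. The U0126 gene capture table appears with identical content under the sustained and the brief label, and its 14 columns were used once, under the sustained label. The effect of U0126 on the brief response in the gene capture was therefore not analysed here. In both total RNA tables the column of vehicle brief 60 min replicate 2 equals that of U0126 sustained 60 min replicate 2, and both were left out. Those groups keep 1 replicate, which is assumed to vary like the others. The 13 unstimulated columns repeated in the brief table were counted once, 1 column that matched no sample was not used, and visual cortex headers that read sl217 and sl317 were taken as slips for SL327.

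Depth was recovered as whole reads per column, and the intervals it gives cover counting error only, since PCR copies count as reads. The median was 2014944 reads in the U0126 gene capture, 2573197 in the cycloheximide experiment, 255966 for captured enhancers, 6249 for enhancers in total RNA and 17945701 for introns. It was 2004698 and 2024965 in the brief and sustained visual cortex tables.

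Tests ran in limma 3.58.1 under R 4.3.3, on log2 of the value plus a pseudocount, with all groups of an experiment in 1 fit. The pseudocount was the 10th percentile of the non-zero values, and features whose mean lay below it were left out. It was 0.00936 for the gene capture (277 genes tested), 0.0115 for cycloheximide (283), 0.248 for introns (21520 transcripts), 0.0304 for enhancers in total RNA (372), 0.229 for captured enhancers (343), and 0.00317 and 0.00341 for the sustained and brief visual cortex tables (266 and 260). Fold changes on this scale understate changes of genes near the pseudocount. Cultures of 1 dissection that were grown separately were averaged to 1 replicate, and each visual cortex sample counted as 1. Adjusted p are Benjamini-Hochberg values over the features of a table, with a threshold of 0.05. Responses that the design tests over several times used a moderated F test, and the change given is then that of the time with the largest one. Interactions test whether the response differs with the drug. edgeR 4.0.16 (quasi-likelihood) was run on the recovered reads of the total RNA tables as an alternative chosen after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.

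The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. That rule took, per contrast, the 10 largest rises and 5 largest falls among features past 0.05 whose replicates all lay on 1 side of the reference mean. It added up to 4 members of each list with the smallest and up to 4 with the largest adjusted p, and the markers Fos, Npas4, Arc, Egr1, Nr4a1, Bdnf, Nptx2 and Pcsk1. For enhancers it took every region assigned to Fos, Arc, Nr4a1 or Bdnf. The 16 lists hold 230 members: immediate-early transcription factors (22), ERK pathway feedback regulators (14), cAMP and CREB feedback genes (12), synaptic and dendritic effectors (20), secreted factors (25), late response genes (19), growth arrest and turnover regulators (17), chromatin regulators (11), housekeeping genes (33), and markers of excitatory (8) and inhibitory neurons (10), astrocytes (8), the oligodendrocyte lineage (9), microglia (8), endothelial and mural cells (7) and dividing progenitors (7). Lists with 5 or more measured members were tested with fry, and introns entered them with 1 transcript per gene.

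Replicate numbers were checked for pairing by the correlation of residuals between same-numbered samples. All 56 of 56 pairs exceeded 0.1 for introns (lowest 0.841) and for enhancers in total RNA (lowest 0.208), so the replicate numbers of the labels pair the samples there. The planned main fits of these tables do not use this pairing. Their changes, SE and adjusted p are unpaired, and counts that moved with the replicate number as a block are given beside the results. The tests were run on simulated data. For the gene capture at 60 min of sustained activity, 60% of genes changed by a log2 of 1 and 95% of those changed by 2 were recovered, with 1 false call among 237. The shares were 60% and 95% for cycloheximide vehicle (4 among 243), 47% and 77% for introns at 60 min (4 among 21320), 0% and 20% for enhancers in total RNA with sustained activity, and 0% and 5% for captured enhancers at 60 min of sustained activity. They were 95% and 100% for 30 min of sustained light and 90% and 100% for brief light. With edgeR they were 80% and 100% for the introns and 90% and 100% for the enhancers in total RNA. The edgeR counts were simulated with a set dispersion not estimated from the data, and only for features with more reads. Those shares cannot be set against the shares of limma, which used the spread of the data.

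Alternatives were a pseudocount at the 1st percentile, no filter, scaling by the median log ratio over all features kept, the replicate number as a block, the first culture of each dissection alone, and leaving out each replicate. Those chosen after the data were seen were keeping the duplicated column under either label, edgeR, leaving out a shallow library, and subsets of replicate numbers.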

Results

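RNA was measured in cultured mouse cortical neurons and in the visual cortex of adult male mice, to compare the responses to brief and to sustained neuronal activity and to ask how they depend on MEK, the kinase that activates ERK. Cultures received U0126, a MEK inhibitor, or DMSO as vehicle, and animals received SL327, another MEK inhibitor, or corn oil as vehicle. The labels do not say how activity was evoked in culture. Captured libraries were enriched with RNA baits for a gene panel of 47 control genes, which set the scale of each library, and 251 others (activity-regulated gene capture) or for 351 enhancer regions (enhancer capture), and total RNA libraries gave read levels over the introns of 27962 transcripts and over 940 enhancer regions.

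Vehicle cultures of the gene capture had 7 replicates in the unstimulated group, 3 at 20 min, 7 at 60 min and 6 at 360 min of sustained activity, and 3, 7 and 5 at the same times after brief activity. U0126 cultures had 3 replicates each when unstimulated, at 20 min and at 60 min, and 2 at 360 min. The cycloheximide experiment had 2 samples in each of 4 groups, and total RNA had 2 replicates per group except 1 in vehicle at 60 min after brief activity and 1 in U0126 at 60 min of sustained activity. Enhancer capture had 4 replicates per group, and the visual cortex groups had 2 or 3 samples. Captured libraries held between 8498 and 7695002 reads over the panel, with a median of 2077995 in the sustained vehicle table and 1611058 in the brief vehicle table. The intron table held between 10486281 and 25945718 reads per library, the enhancer regions in total RNA between 3193 and 9145, and the captured enhancers between 48309 and 1073939. Visual cortex libraries held between 270449 and 5744389 reads. Changes are given as log2 fold changes with their SE from the fit, and group levels as the mean ± SD of n replicates.

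Transcription factor genes of the immediate-early class led the response to sustained activity in culture. At 20 min, 6 of 277 genes passed the limma test, all of them upward and all on the list of immediate-early transcription factors (6 of 16 measured, 6 adjusted over the list alone). Fosb, a subunit of the AP-1 factor, rose by a log2 fold change of 4.61 ± 0.77 (adjusted p = 4.0e-05), from a normalised read count of 0.0104 ± 0.0098 (n = 7) to 0.435 ± 0.083 (n = 3). Npas4, an activity-dependent neuronal transcription factor, rose by 3.91 ± 0.49 (adjusted p = 1.8e-07), and Fos, another AP-1 subunit, by 3.68 ± 0.52 (adjusted p = 1.5e-06). Junb, Egr1 and Ier2 rose by 2.44 ± 0.51, 2.24 ± 0.56 and 1.40 ± 0.33. At 60 min (n = 7 in both groups), 36 genes passed, again all upward: Fos reached 9.77 ± 2.9 against 0.176 ± 0.21, a log2 fold change of 6.21 ± 0.40 (adjusted p = 9.4e-17). Npas4 rose by 6.39 ± 0.38 and Nr4a1, an orphan nuclear receptor, by 4.86 ± 0.35. Arc, which controls AMPA receptor endocytosis at synapses, rose by 3.73 ± 0.43 (adjusted p = 1.7e-09). Pcsk1, a convertase that processes peptide precursors, rose by 2.14 ± 0.29 (adjusted p = 1.1e-07).

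Of the fixed lists at 60 min, 14 of 16 immediate-early transcription factors rose (16 adjusted over the list alone), with a median log2 fold change of 2.96. Growth arrest and turnover regulators rose in 4 of 7 (4 adjusted over the list alone), among them Gadd45b by 3.10 ± 0.30 (adjusted p = 2.1e-11). The cAMP and CREB feedback genes rose in 4 of 9 (4 adjusted over the list alone), and the ERK pathway feedback regulators in 3 of 8 (3 adjusted over the list alone). Secreted factors rose in 3 of 10, synaptic and dendritic effectors in 2 of 11 and late response genes in 2 of 12 (4, 2 and 2 adjusted over the list alone). By fry, which asks whether the genes of a list move on balance one way, each of these 7 lists moved upward, with adjusted p between 2.1e-15 and 0.00046. The growth factor gene Bdnf stood at a log2 fold change of 0.62 ± 0.29 (adjusted p = 0.221) and Nptx2, a pentraxin that clusters AMPA receptors, at 0.10 ± 0.41 (adjusted p = 0.942). Rescaling the libraries on all genes kept moved the median of all genes by 0.19 on the log2 scale, and 32 genes then passed.

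After 360 min of sustained activity (n = 6) Pcsk1, already raised at 60 min, rose by a log2 fold change of 6.63 ± 0.30 (adjusted p = 4.3e-22) to 8.12 ± 3.3, and Bdnf by 5.00 ± 0.31 (adjusted p = 1.1e-17), from 0.0565 ± 0.043 to 1.84 ± 0.42. Scg2, a granin of secretory vesicles, rose by 4.01 ± 0.40, Vgf, a neuropeptide precursor, by 4.25 ± 0.53, and Nptx2 by 2.88 ± 0.43 (adjusted p = 1.6e-07). Fos and Npas4 were still raised, by 5.47 ± 0.42 and 6.36 ± 0.40. Arc stood at 0.80 ± 0.45 (adjusted p = 0.101) and Egr1 at 0.72 ± 0.45 (adjusted p = 0.144). Late response genes rose in 11 of 12, secreted factors in 9 of 10, synaptic and dendritic effectors in 9 of 11 and immediate-early transcription factors in 14 of 16, with the same counts adjusted over the list alone. The cAMP and CREB feedback genes rose in 9 of 9, the ERK pathway feedback regulators in 7 of 8 and the growth arrest regulators in 6 of 7, again with the same counts adjusted over the list alone.

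In all, 193 of 277 genes rose and 4 fell at 360 min (median log2 fold change 1.5). High list counts alone thus show no rise specific to a list. All 4 that fell were control genes, among them Ubox5 (-0.76 ± 0.15), Cog4 (-0.48 ± 0.18) and Apex1 (-0.55 ± 0.24). Rescaling the libraries on all genes kept shifted every value by 1.38 at the median and left 51 genes up and 65 down (44.0% upward in place of 98.0%). This rescaling sets the median change near 0 by construction. It takes out a broad rise and divides the calls between both directions. On that scale late response genes rose in 10 of 12, immediate-early transcription factors in 9 of 16 and secreted factors in 6 of 10, while the ERK pathway feedback regulators rose in 1 of 8 and the growth arrest regulators split into 1 up and 1 down. The 2 measured housekeeping genes and the 2 measured chromatin genes rose on the deposited scale, and neither housekeeping gene did after rescaling.

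Brief activity raised the same kind of transcription factor genes at 20 and 60 min. At 20 min (n = 3) Fos rose by a log2 fold change of 3.52 ± 0.52 (adjusted p = 4.3e-06), Npas4 by 3.45 ± 0.49 (adjusted p = 3.6e-06) and Fosb by 3.92 ± 0.77 (adjusted p = 0.00077). The 6 genes that passed were all immediate-early transcription factors (6 of 16, 7 adjusted over the list alone), and 3 passed without brief 20 min replicate 7. At 60 min (n = 7) 15 genes passed, all upward, among them Fos by 4.10 ± 0.40 (adjusted p = 1.8e-10), Egr1 by 2.72 ± 0.43, Nr4a1 by 2.48 ± 0.35 and Arc by 1.71 ± 0.43 (adjusted p = 0.0059). Dusp6, a phosphatase that inactivates ERK, rose by 1.5 ± 0.38. Immediate-early transcription factors rose in 10 of 16 (11 adjusted over the list alone), cAMP and CREB feedback genes in 2 of 9 (4 adjusted over the list alone) and late response genes in 1 of 12 (2 adjusted over the list alone). One of the 7 libraries at 60 min was shallow, with 8498 reads and 100 genes at 0. In replicates 5 to 7 alone, chosen after the data were seen, 8 genes passed.

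At 360 min after brief activity (n = 5) 0 of 277 genes passed in limma, and 9 had an unadjusted p below 0.05. Fos stood at 0.124 ± 0.059 and Npas4 at 0.0235 ± 0.0079, log2 fold changes of -0.07 ± 0.44 and 0.23 ± 0.42. Pcsk1 stood at 0.92 ± 0.32 (adjusted p = 0.6). The median of all genes was 0.07. By fry the secreted factors moved upward on balance (adjusted p = 0.0494), with 0 of 10 members passing over the panel and 0 adjusted over the list alone. Among late response genes 0 of 12 passed, and 2 adjusted over the list alone.

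**Figure D1:**
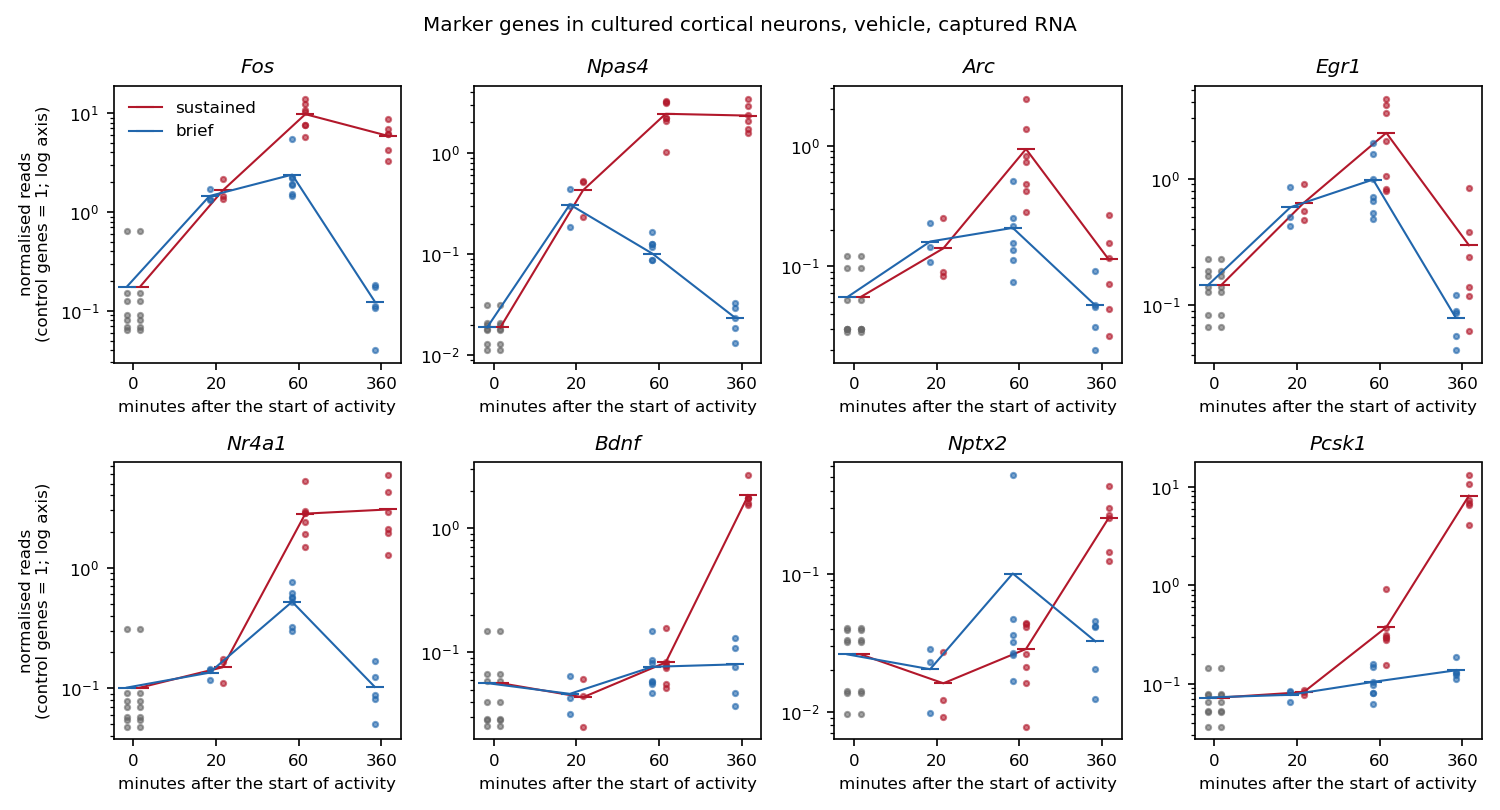
Normalised reads (control genes = 1, log axis) of 8 marker genes against time in vehicle cultures, unstimulated (grey), sustained (red) and brief (blue), with a point per replicate and lines or dashes at the means. Bdnf reached a mean of 1.84 at 360 min of sustained activity and 0.08 at 360 min after brief activity, while Fos at 20 min stood at 1.65 and 1.45.

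**Figure D2:**
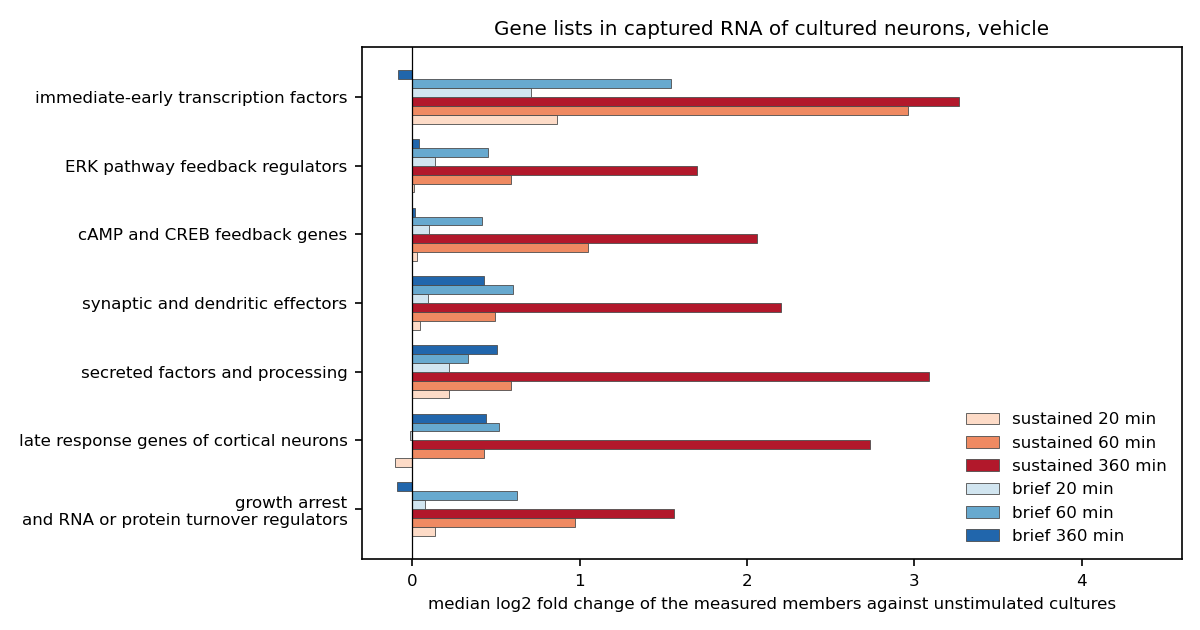
Median log2 fold change against unstimulated cultures of 7 fixed gene lists in the gene capture, with a bar for each of 6 vehicle contrasts (sustained and brief at 20, 60 and 360 min). The late response genes reached a median of 2.74 at 360 min of sustained activity and 0.44 at 360 min after brief activity.

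A direct test of sustained against brief activity at each time asked which genes tell the patterns apart. At 20 min (n = 3 each) 0 of 277 genes passed in limma and 0 had an unadjusted p below 0.05, and Fos differed by 0.16 ± 0.61. At 60 min (n = 7 each) 21 genes were higher with sustained activity, led by Npas4 at a log2 difference of 4.74 ± 0.38 (adjusted p = 3.1e-13), Fosb at 3.26 ± 0.60 and Gadd45b at 2.47 ± 0.30. Arc was higher by 2.01 ± 0.43 (adjusted p = 0.00056), Pcsk1 by 1.63 ± 0.29 and Dusp1, a MAP kinase phosphatase, by 2.42 ± 0.52, while Egr1 differed by 1.09 ± 0.43 (adjusted p = 0.152). Immediate-early transcription factors were higher in 9 of 16 (11 adjusted over the list alone), cAMP and CREB feedback genes in 2 of 9 (5 adjusted over the list alone) and growth arrest regulators in 2 of 7 (2 adjusted over the list alone). Late response genes were higher in 2 of 12 (2 adjusted over the list alone), with a fry adjusted p of 0.239. In replicates 5 to 7 alone 13 genes passed.

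At 360 min, 184 genes were higher and 3 lower with sustained than after brief activity. Pcsk1 differed by 5.71 ± 0.33 (adjusted p = 2.9e-18), Npas4 by 6.14 ± 0.43 (adjusted p = 1.6e-15), Bdnf by 4.47 ± 0.33 (adjusted p = 5.6e-15) and Nptx2 by 2.63 ± 0.46. Late response genes were higher in 12 of 12, cAMP and CREB feedback genes in 9 of 9, immediate-early transcription factors in 14 of 16 and synaptic and dendritic effectors in 10 of 11, with the same counts adjusted over the list alone. Rescaling on all genes kept moved the median by 1.30, and 42 genes were then higher and 59 lower, so that 41.6% of calls were upward in place of 98.4%. The late response genes were then higher in 7 of 12 and the immediate-early transcription factors in 10 of 16. The division of calls between both directions follows from setting the median near 0.

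Cultures treated with U0126 tested whether the response depends on MEK. The gene capture table for U0126 was deposited with identical content under the sustained and the brief label, and its 14 columns are used here under the sustained label. With that caveat, Npas4 rose in U0126 at 20 min by a log2 fold change of 3.48 ± 0.58 (adjusted p = 0.00011), and at 60 min Npas4 rose by 6.23 ± 0.58 and Fos by 5.51 ± 0.61 (adjusted p = 3.7e-09). Npas4 was the 1 gene that passed in U0126 at 20 min, against 6 genes in vehicle. At 60 min 20 passed in U0126 and 36 in vehicle, which had more replicates. Egr1 at 20 min stood at 0.0629 ± 0.0088 in U0126 and 0.642 ± 0.23 in vehicle. Arc stood at 1.05 at 60 min in U0126 (adjusted p = 0.497), a level of 0.0806 ± 0.025 (n = 3) against 0.936 ± 0.76 (n = 7) in vehicle. At 360 min (n = 2) 136 genes rose in U0126, among them Pcsk1 by 6.77 ± 0.50 and Bdnf by 4.03 ± 0.50, and 4 fell. The interaction of U0126 with the sustained response over 3 times passed in 0 of 277 genes in limma, with 5 at an unadjusted p below 0.05. Its part at 60 min was -2.68 ± 0.78 for Arc (adjusted p = 0.193), and its part at 360 min was -0.96 ± 0.59 for Bdnf (adjusted p = 0.98). By fry the growth arrest regulators responded less with U0126 at 60 min (adjusted p = 0.0439), with 0 of 7 passing over the panel and 2 adjusted over the list alone. In unstimulated cultures U0126 changed 0 genes in limma, with 15 at an unadjusted p below 0.05. That count depended on single libraries. Without vehicle unstimulated replicate 5 there were 6 genes lower, without replicate 4 there were 2 and without replicate 6 there was 1. Settings moved it too, to 3 with the first culture only and 3 with the replicate number as a block, 2 without the shallow brief 60 min library and 1 with the lower pseudocount. Egr1 stood there at 0.0199 ± 0.0059 (n = 3) against 0.143 ± 0.058 (n = 7), a difference of -2.22 ± 0.56 (adjusted p = 0.0696).

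The cycloheximide experiment compared the response to 360 min of sustained activity with and without this blocker of protein synthesis (n = 2 in each group). The drug also changed unstimulated cultures, with 26 genes higher and 6 lower. A smaller response can thus go with a raised starting level. Egr1, whose response was smaller (-2.79 ± 0.71, adjusted p = 0.028), went from 1.88 ± 0.17 to 1.43 ± 0.55 with the drug and from 0.0213 ± 0.015 to 0.167 ± 0.12 in vehicle. Nptx2 reached 0.0639 ± 0.022 with the drug against 0.0229 ± 0.0080 unstimulated, and its response was smaller than in vehicle by a log2 interaction of -2.25 ± 0.63 (adjusted p = 0.033). The responses of the potassium channel gene Kcna1 (-3.30 ± 0.50, adjusted p = 0.0021), the ERK inhibitor gene Spry4 (-3.43 ± 0.78, adjusted p = 0.014) and Dennd2c (-4.45 ± 0.60, adjusted p = 0.0013) were also smaller, and so was that of Acan, which encodes the perineuronal net proteoglycan aggrecan. Larger responses with cycloheximide were seen for Cwc25 (3.12 ± 0.47, adjusted p = 0.0021), the somatostatin receptor gene Sstr2 (2.70 ± 0.52) and Gadd45b (2.72 ± 0.79). Pcsk1 rose with cycloheximide by 7.92 ± 0.41 and Npas4 by 7.00 ± 0.35, and neither interaction passed (1.73 ± 0.58 with adjusted p = 0.0635 for Pcsk1, 0.66 with adjusted p = 0.45 for Npas4). For Bdnf, which rose by 5.59 ± 0.35 in vehicle and by 4.37 ± 0.35 with cycloheximide, the interaction was -1.21 ± 0.50 (adjusted p = 0.117).

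Of 283 genes tested there, 209 rose and 2 fell in vehicle, and the response was larger with cycloheximide for 14 and smaller for 31. Late response genes rose in 13 of 13 in vehicle, and their responses were smaller with cycloheximide in 3 of 13 and larger in 0 (3 and 1 adjusted over the list alone), with a fry adjusted p of 0.0113 downward. Immediate-early transcription factors rose in 15 of 16 in vehicle, and 1 response was larger and 3 were smaller with cycloheximide (2 and 3 adjusted over the list alone). The smaller ones were those of Egr1, Egr2 and Fos, which the drug alone had raised in unstimulated cultures. The mean level of Fos was 44.5 with cycloheximide and 4.81 in vehicle after 360 min, against 1.20 and 0.0267 in unstimulated cultures. Rescaling on all genes kept moved the interaction by -0.47 at the median and gave 20 larger and 12 smaller responses, so that 62.5% of calls were upward in place of 31.1%. The vehicle response split into 51 up and 60 down (45.9% upward in place of 99.1%) after a shift of 1.70, a division built in by setting the median near 0. The interaction count moved between 9 without cycloheximide unstimulated replicate 1 and 74 without vehicle sustained 360 min replicate 2. Leaving out 4 further libraries singly gave 13 (cycloheximide unstimulated replicate 2), 14 and 23 (cycloheximide sustained 360 min replicates 1 and 2), and 24 (vehicle unstimulated replicate 2).

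**Figure D3:**
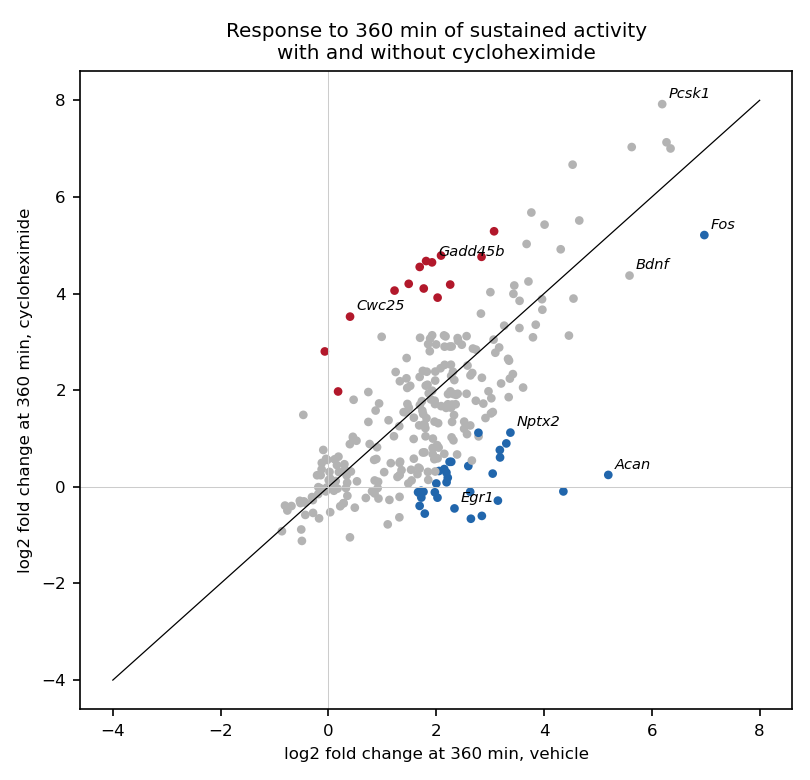
Log2 fold change of each gene at 360 min of sustained activity in vehicle (horizontal axis) and in cycloheximide (vertical axis), with genes whose response was larger (red) or smaller (blue) with the drug and the line of equality. Pcsk1 lay at 6.19 in vehicle and 7.92 in cycloheximide, and Nptx2, at 3.38 and 1.12, is among the 31 genes with a smaller response.

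Introns report RNA that has not yet been spliced, over 21520 transcripts of 13492 genes. At 20 min of sustained activity (n = 2 each) Fosb rose by a log2 fold change of 6.73 ± 0.30 (adjusted p = 3e-05), from 0.172 ± 0.067 to 43.5 ± 6.8 RPM, Npas4 by 5.86 ± 0.33 and Nr4a1 by 4.6 ± 0.26. Homer1, a scaffold of the postsynaptic density, rose by 2.43 ± 0.22, from 38.2 ± 9.5 to 204 ± 1.3. Zfp329 (-1.28 ± 0.19, adjusted p = 0.0388) and Zfp109 (-0.91 ± 0.11), both zinc-finger genes, fell. At 60 min Pcsk1 rose by 5.64 ± 0.21 (adjusted p = 4.4e-06), from 3.34 ± 0.65 to 177 ± 26, Nr4a1 by 6.55 ± 0.26 and Bdnf by 2.24 ± 0.33 (adjusted p = 0.0043). Dusp7, another ERK phosphatase gene, fell by 2.0 ± 0.24 (adjusted p = 0.0017), from 8.76 ± 1.3 to 1.98 ± 0.15, and Zfp109 fell by 1.86 ± 0.11.

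Immediate-early transcription factors rose in introns in 9 of 16 at 20 min (13 adjusted over the list alone) and in 13 of 16 at 60 min (15 adjusted over the list alone), with fry adjusted p of 5.76e-06 and 2.65e-07. At 60 min growth arrest regulators rose in 8 of 15 (9 adjusted over the list alone), late response genes in 7 of 17 (7), cAMP and CREB feedback genes in 6 of 11 (8), and ERK pathway feedback regulators in 4 of 14 (4). Synaptic and dendritic effectors rose in 6 of 17 (7 up and 1 down adjusted over the list alone), and secreted factors in 4 of 16 while 1 fell (4 and 1 adjusted over the list alone). Chromatin genes rose in 1 of 11 (1 adjusted over the list alone) and housekeeping genes in 2 of 33 (2), with fry adjusted p of 0.231 and 0.198. Markers of excitatory neurons (8 measured), inhibitory neurons (9), astrocytes (8), the oligodendrocyte lineage (7), microglia (5), endothelial and mural cells (6) and dividing progenitors (6) passed in 0 members each, also adjusted over the list alone, with median log2 fold changes between -0.33 and 0.14. With the replicate number as a block, fry gave adjusted p of 0.0048 for the oligodendrocyte lineage and 0.0272 for astrocytes, both downward (0.249 and 0.767 without the block), and 0.0318 upward for housekeeping genes. At 20 min the block gave upward fry calls for ERK pathway feedback regulators (0.0037), secreted factors (0.0351) and growth arrest regulators (0.00067), each 0.138 without it.

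Over all transcripts, 48 rose and 12 fell at 20 min, and 675 rose and 998 fell at 60 min. With the replicate number as a block 201 changed at 20 min, 75 of them downward, and 1580 rose and 3247 fell at 60 min. Rescaling on all transcripts kept moved the median by -0.09 and gave 811 up and 528 down at 60 min, 60.6% upward in place of 40.3%. edgeR on the recovered reads called 41 up and 0 down at 20 min, and 810 up and 500 down at 60 min. Each of the 4 replicates left out singly lowered the count, to between 13 (without sustained 20 min replicate 2) and 29 (without sustained 20 min replicate 1) at 20 min, and to between 509 (without unstimulated replicate 2) and 754 (without sustained 60 min replicate 1) at 60 min. Keeping the duplicated column as vehicle at 60 min after brief activity left 15 at 20 min and 974 at 60 min (362 up, 612 down).

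After brief activity introns of the same factor genes were raised at 20 min (n = 2). Fosb rose by a log2 fold change of 5.56 ± 0.30 (adjusted p = 0.00018), Fos by 4.78 ± 0.51 (adjusted p = 0.0073) and Npas4 by 4.73 ± 0.33, while Btg2, an antiproliferative gene, rose by 1.94. In all 23 transcripts rose and 1 fell, which became 140 and 44 with the block. Each of the 4 replicates left out singly lowered the total, to between 7 (without brief 20 min replicate 1) and 14 (without unstimulated replicate 2). With the duplicated column kept as vehicle 12 passed. Immediate-early transcription factors rose in 7 of 16 (13 adjusted over the list alone, fry adjusted p = 1.15e-05) and late response genes in 1 of 17 (6 adjusted over the list alone). The block added fry calls for secreted factors (0.0127, 0.0590 without it) and growth arrest regulators (0.0004, 0.0612 without it). At 60 min, where 1 library was used, 0 transcripts passed in limma and in edgeR, 1500 had an unadjusted p below 0.05 in limma, 51 passed with the block (15 up, 36 down) and 12 with no filter. Fos stood there at 11.5 (adjusted p = 0.323), and the immediate-early list passed in 0 of 16 (7 adjusted over the list alone, fry adjusted p = 0.0319). With the block fry also called ERK pathway feedback regulators (0.0434), synaptic effectors (0.0140), secreted factors (0.0457) and growth arrest regulators (0.0434).

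Introns of Fosb, Pcsk1 and Npas4 were higher at 60 min of sustained than after brief activity, by log2 differences of 5.27 ± 0.36 (adjusted p = 0.00105), 4.82 ± 0.25 (adjusted p = 0.00043) and 4.61 ± 0.40 (adjusted p = 0.0039). Pcsk1 stood at 177 ± 26 (n = 2) against 5.99 in the single brief library, and Crem, a cAMP-responsive repressor gene, was higher by 3.12. Dusp7 was lower with sustained activity (-2.11 ± 0.30, adjusted p = 0.0314). Over 20 and 60 min, 122 transcripts had their largest difference upward and 23 downward (525 and 297 with the block), while at 20 min alone 0 passed in limma and 346 had an unadjusted p below 0.05. Immediate-early transcription factors differed in 6 of 16 (14 up and 1 down adjusted over the list alone), and at 60 min alone cAMP and CREB feedback genes were higher in 4 of 11 (6 adjusted over the list alone). The ERK pathway feedback regulators had a fry adjusted p of 0.0615 at 60 min, and 0.0045 with the block. Leaving out single replicates gave between 51 (without sustained 60 min replicate 1) and 98 (without sustained 20 min replicate 1). Keeping the duplicated column as vehicle at 60 min after brief activity gave 0. Keeping it as U0126 at 60 min of sustained activity gave 222. The source of this column was not tested, so the 0 alone does not show a weak difference.

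With U0126 the early intron response of some factor genes was lower in value, and the test across all transcripts at single times, without the replicate block, passed for Egr2 alone. At 20 min after brief activity the interaction for Egr2, a zinc-finger factor, was -3.55 ± 0.33 (adjusted p = 0.0293), while Nr4a1 (-2.99 ± 0.37, adjusted p = 0.117), Egr1 (-2.86 ± 0.42, adjusted p = 0.243) and Fos (-3.01 ± 0.72) did not pass. At 20 min of sustained activity Egr1 stood at 0.718 ± 0.24 in U0126 against 12.3 in vehicle, an interaction of -3.14 ± 0.42 (adjusted p = 0.309). Npas4 still rose in U0126 at 20 min, by 5.36 ± 0.33 (sustained, adjusted p = 0.00037) and 3.5 ± 0.33 (brief, adjusted p = 0.0088), and at 60 min of sustained activity (n = 1) Pcsk1 rose by 6.12 ± 0.25. Immediate-early transcription factors responded less on balance at 20 min, by fry, in the sustained (adjusted p = 0.0168) and the brief pattern (adjusted p = 0.0034), each with a median interaction of -1.16. Of their 16 members 0 and 1 passed (7 and 9 adjusted over the list alone), and at 60 min fry gave 0.878 and 0.713. With the block the synaptic effectors (0.0027 and 0.0037) and growth arrest regulators (0.0062 and 0.0037) also responded less at 20 min in the sustained and the brief pattern, and late response genes (0.0192) in the brief one.

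Over both times 0 transcripts passed for either interaction in limma and in edgeR, with 382 (sustained) and 441 (brief) at an unadjusted p below 0.05, while 4 and 2 passed with the block and 8 and 10 with no filter. In unstimulated cultures U0126 changed 0 transcripts in limma, with 393 at an unadjusted p below 0.05. There the ERK pathway feedback regulators lay at a median of -0.48, with 0 of 14 passing, 5 down adjusted over the list alone, and fry adjusted p of 0.105 (0.0033 downward with the block).

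Enhancer regions, given by their position in build mm9 as deposited and the gene the table names, were read in total RNA to ask whether they respond too (372 tested, n = 2). The region named for Omg at chr11:74985460-74986620 rose with sustained activity by a log2 fold change of 6.01 ± 0.48 (adjusted p = 3.6e-05), from 0.302 ± 0.035 to 19.2 ± 1.1 RPM at 60 min. The Fos region at chr12:86818760-86820490 rose by 4.47 ± 0.54 (adjusted p = 0.000405), the Nr4a1 region at chr15:101083840-101085090 by 3.81 ± 0.50 and the Scg2 region at chr1:79428480-79429890 by 3.68 ± 0.63. The Stam region at chr2:13979320-13980410 fell by 3.13 ± 0.63. After brief activity the same Fos region rose by 4.07 ± 0.54 (adjusted p = 0.006), the Omg region by 3.01 ± 0.48 and an Egr3 region at chr14:70474130-70475420 by 3.44 ± 0.47 (adjusted p = 0.006). A Per1 region at chr11:68906450-68909430 was higher at 60 min of sustained than after brief activity by 4.22 ± 0.60 (adjusted p = 0.0175), at 2.67 ± 0.18 against 0.114 (n = 1).

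Over 20 and 60 min together 48 regions passed with sustained activity (43 up, 5 down), 9 with brief activity (7 up, 2 down) and 21 between them (20 higher, 1 lower with sustained activity). Rescaling on all regions kept moved the median by 0.69 for sustained activity and gave 27 up and 8 down, 77.1% upward in place of 89.6%. With the replicate number as a block 25 regions passed after brief activity, 16 did in edgeR and with no filter, and 2 with the first culture only. Kept as vehicle at 60 min after brief activity, the duplicated column (source not tested) left 24 regions with sustained activity and 0 between patterns. Between the patterns the first culture only left 8, and rescaling or the lower pseudocount 11 each. The sustained count fell to between 19 (without unstimulated replicate 2) and 28 (without sustained 60 min replicate 2) for 4 of the 6 replicates. The brief count fell to 0 and 3 without brief 20 min replicates 1 and 2, and the difference to 0 without sustained 60 min replicate 1 and to 13 or fewer without any other. U0126 changed the sustained response of 0 regions in limma and in edgeR, with 15 at an unadjusted p below 0.05. It lowered the brief response of the Egr3 region (-4.11 ± 0.67, adjusted p = 0.0254), a call that ended without any 1 of 8 replicates and with the duplicated column kept under either label. For this response 2 regions passed in edgeR and 5 with no filter.

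Captured enhancers (343 tested, n = 4) gave the same question at greater depth per region. The Nr4a1 region at chr15:101083840-101085090 rose at 20 min of sustained activity by a log2 fold change of 4.59 ± 0.72 (adjusted p = 4.8e-05), from a signal of 0.361 ± 0.22 to 15.8 ± 10. At 60 min the Omg region rose by 6.87 ± 1.08 (adjusted p = 1.9e-05) to 117 ± 81, and the Scg2 region by 4.74 ± 0.70 (adjusted p = 1.2e-05). An Arc region at chr15:74509120-74510330 rose at 60 min of sustained activity by 2.79 ± 0.72 and at 20 min of brief activity by 2.87 ± 0.72 (adjusted p = 0.0365). Sustained activity left the Nr4a1 region higher at 60 min than brief activity did, by 3.41 ± 0.72 (adjusted p = 0.0040), with 14.8 ± 8.2 against 1.14 ± 0.78. In U0126 the Omg region rose at 60 min of sustained activity by 5.65 ± 1.08 (adjusted p = 0.00048). These means pool libraries of different scale. In replicates 1 and 2 the reads per unit of signal ran from 0.626 to 1106 and 5 to 167 of the 351 regions were at 0, against 319 to 673 reads per unit and 0 to 2 regions in replicates 3 and 4.

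The numbers of captured regions that rose were 4 at 20 min and 34 at 60 min of sustained activity, 6 at 20 min of brief activity, and 0 at 60 min after brief activity in limma (5 at an unadjusted p below 0.05). The patterns differed in 7 regions. U0126 changed 0 responses in limma in either pattern, with 0 (sustained) and 6 (brief) at an unadjusted p below 0.05. Without the shallow U0126 library of 60 min after brief activity, left out after the data were seen, these counts were 19 and 57, 13 and 1, and 23 for the difference. The first culture only gave 7 at 20 min of sustained activity and 3 for the difference, and the lower pseudocount gave 3 at 20 min of brief activity. Counts differed between replicates 1 and 2 and replicates 3 and 4. Within replicates 1 and 2, 0 and 2 regions passed at 20 and 60 min of sustained activity, 0 at either time of brief activity and 0 for the difference. Within replicates 3 and 4 these counts were 42 and 97, 16 and 1, and 56. Rescaling on all regions kept moved the medians by 0.51 at 20 min and 0.76 at 60 min of sustained activity, and gave 19 up at 20 min, 28 up and 6 down at 60 min (82.4% upward in place of 100%), 1 at 60 min after brief activity and 22 for the difference. Of 8 replicates left out singly, 6 moved the count at 20 min of sustained activity, to between 1 (without unstimulated replicate 1) and 8 (without sustained 20 min replicate 3). At 20 min of brief activity 6 did so, to between 0 (without unstimulated replicate 1) and 10 (without brief 20 min replicate 3). At 60 min of sustained activity 5, 14 and 22 regions were left without sustained 60 min replicates 1 and 2 and unstimulated replicate 3. The difference between patterns fell to between 1 and 4 for 12 of 16 replicates.

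In the visual cortex of animals given corn oil, sustained light raised early response genes within 30 min (3 samples in light, 2 in the dark). Btg2 rose by a log2 fold change of 2.45 ± 0.68 (adjusted p = 0.0149), from 0.246 ± 0.042 to 1.74 ± 1.1, Junb by 2.33 ± 0.52 (adjusted p = 0.0048), Gadd45b by 1.69 ± 0.26 (adjusted p = 0.00079) and Nr4a1 by 1.43 ± 0.49 (adjusted p = 0.0394). Cyr61, a secreted matrix protein gene, rose by 2.62 ± 0.68. Fos stood at 0.544 ± 0.40 against 0.114 ± 0.027 (adjusted p = 0.0823) and Arc at 2.27 ± 1.6 against 0.584 ± 0.11 (adjusted p = 0.117), and 1 of the 3 light samples held Fos at 0.0876 and Arc at 0.373. At 150 min Bdnf rose by 1.29 ± 0.24 (adjusted p = 0.0028), Nptx2 by 1.04 ± 0.20 (adjusted p = 0.0028), Pcsk1 by 1.08 ± 0.19 and Ptgs2, which encodes cyclooxygenase 2, by 1.19 ± 0.18. Immediate-early transcription factors rose in 10 of 16 at 30 min (12 adjusted over the list alone) and 4 of 16 at 150 min (10 adjusted over the list alone), and late response genes in 1 of 12 and 5 of 12 (1 and 6 adjusted over the list alone).

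Of 266 genes, 88 rose and 3 fell at 30 min, and 24 rose and 1 fell at 150 min. Rescaling on all genes kept moved the medians by 0.30 and 0.15 and left 12 up and 9 down at 30 min (57.1% upward in place of 96.7%) and 11 up and 4 down at 150 min (73.3% in place of 96.0%). The immediate-early list then rose in 3 of 16 at 30 min. Setting the median near 0 lowers the changes of all genes, so part of this loss is built in. Without corn oil dark 30 min replicates 1 and 2, 37 and 25 genes passed at 30 min, and without corn oil dark 150 min replicates 1 and 2, 16 and 7 passed at 150 min.

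With SL327, 1 response to sustained light was larger and 52 were smaller at 30 min, and 1 was larger at 150 min. This difference between times was not tested. The response of Fosl2, an AP-1 subunit gene, was lower with SL327 at 30 min (-2.09 ± 0.30, adjusted p = 0.0018 over both times), with 0.0929 ± 0.010 in light (n = 3) against 0.233 ± 0.044 in the dark (n = 2). The responses of the clock gene Per2 (-2.07 ± 0.33, adjusted p = 0.0023), of Sik1, a kinase that restrains CREB (-2.08 ± 0.39, adjusted p = 0.00775), of Fosb (-2.33 ± 0.49, adjusted p = 0.016) and of Nptx2 (-1.09 ± 0.28, adjusted p = 0.0365) were lower as well. At 30 min immediate-early transcription factors responded less in 8 of 16 (14 adjusted over the list alone), cAMP and CREB feedback genes in 5 of 9 (7), growth arrest regulators in 3 of 7 (5) and ERK pathway feedback regulators in 2 of 8 (5). In the dark SL327 samples of 30 min themselves, Per2 was higher than with corn oil by 1.58 ± 0.25 (adjusted p = 0.0022) and Ptgs2 by 1.44 ± 0.20 (adjusted p = 0.00090), among 30 genes higher and 2 lower (n = 2 each). In light, SL327 samples had 5 genes lower, with Atf3 at -1.07 ± 0.23 and Gadd45b at -1.06 ± 0.24.

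Over both times 1 response was larger and 47 were smaller with SL327. Rescaling on all genes kept moved the median by -0.50 and gave 6 larger and 10 smaller, 37.5% in place of 2.08% upward, with 4 of 16 immediate-early transcription factors lower at 30 min. Of the 20 samples left out singly, 10 lowered the count to between 14 (without corn oil dark 30 min replicate 2) and 31 (without SL327 dark 30 min replicate 1), and 67 passed without corn oil light 30 min replicate 3.

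**Figure D4:**
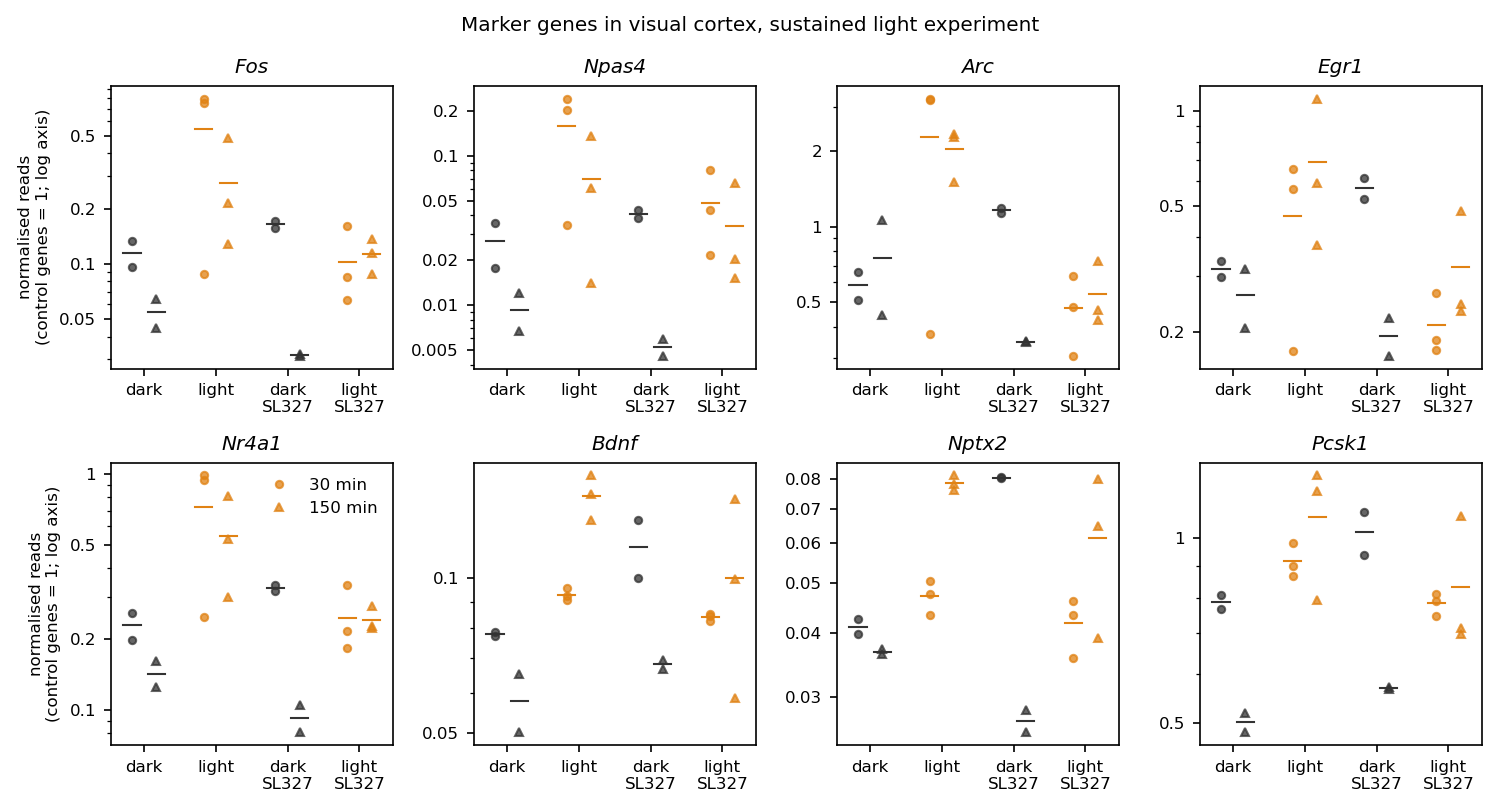
Normalised reads (control genes = 1, log axis) of 8 marker genes in visual cortex, in the dark (black) and in sustained light (orange) with corn oil or SL327, at 30 min (circles) and 150 min (triangles), with a point per sample and lines at the means. Bdnf at 150 min with corn oil stood at 0.145 in light and 0.0577 in the dark.

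Brief light in the visual cortex was measured in a separate table with its own dark samples, and no test here compares it with sustained light. At 30 min (n = 3 each) Btg2 rose by a log2 fold change of 1.38 ± 0.16 (adjusted p = 0.00014), Arc by 0.88 ± 0.19 (adjusted p = 0.0271) and Dusp1 by 0.83 ± 0.18 (adjusted p = 0.0271), and these were the 3 genes of 260 that passed. Immediate-early transcription factors passed in 0 of 14 (6 adjusted over the list alone) and moved upward on balance by fry (adjusted p = 0.0410). One gene was left without corn oil dark 30 min replicate 1, brief light replicate 2 or brief light replicate 3. At 150 min (n = 2) 0 genes passed in limma, with 18 at an unadjusted p below 0.05, and Fos stood at -0.24. SL327 lowered the response of Btg2 at 30 min (-1.52 ± 0.24, adjusted p = 0.0159), the single interaction that passed, and 0 passed without any 1 of 6 samples. In brief light itself at 30 min (n = 3 each), SL327 samples had lower Egr2 (-2.48 ± 0.24, adjusted p = 7.9e-06), Arc (-1.88 ± 0.19, adjusted p = 7.9e-06), Fos (-2.02 ± 0.27, adjusted p = 0.00025) and Dusp6 (-1.64 ± 0.25, adjusted p = 0.00073), among 12 genes lower and 1 higher. In the dark samples of that table at 30 min, Egr2 (-1.63 ± 0.27, adjusted p = 0.00645), Arc (-1.11 ± 0.21, adjusted p = 0.0126) and Dusp6 (-1.23 ± 0.28, adjusted p = 0.0407) were lower with SL327 too. At 150 min in the dark (n = 2 each) Fos (-1.64 ± 0.34, adjusted p = 0.0194) and Spry4 (-1.80 ± 0.39) were lower.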

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

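Of the tests weighed here, those of the U0126 table's label, of the upper control genes, of the time since the start of the experiment, and of the SL327 dark groups and labels were chosen only after the result was seen. The introns of control genes and the splits of samples were set out after the main counts were known and before their own values were.

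The U0126 gene capture table carries a sustained and a brief label with the same content, so at most 1 of them is right. Over the 193 genes raised at 360 min of sustained activity, its 360 min libraries lay a median of 1.45 above vehicle cultures after brief activity (1.36 to 1.45 per library, SD 0.060, 189 of 193 genes higher), which argues against libraries from brief activity. Against vehicle cultures of sustained activity the median difference was -0.25 (-0.286 to -0.163 per library, SD 0.087), which is consistent with libraries from sustained activity in which U0126 may have lowered these genes somewhat. At 60 min, over the 21 genes higher with sustained than after brief activity in vehicle, its libraries lay a median of 1.25 above vehicle brief (0.777 to 1.32 per library, SD 0.287, 19 of 21 genes higher), which argues against brief activity there too, and a median of -0.56 from vehicle sustained (-1.36 to -0.290 per library, SD 0.564, 3 of 21 higher). The source of the 20 min columns stays open, since 0 genes told the patterns apart at that time in vehicle.

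Most panel genes rose after 360 min of sustained activity, by a median of 1.68 over the 230 that are not control genes. If part of the control genes had fallen and left 23 or more of the 47 in place, those would stand at 1.18 or more, but the upper 23 had a median of 0.275 (SD 0.274, 0 genes at that bound), which argues against this. Time since the start of the experiment is argued against by the median of 0.0820 at 360 min after brief activity. A fall of all or nearly all control genes together cannot be told apart from a broad rise, because no table holds a scale free of them at 360 min, and the introns of 46 control genes at 60 min had a median of -0.0707 (1 up, 4 down). A broad rise of the panel genes remains a hypothesis.

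Responses of 52 genes to 30 min of sustained light were lower with SL327. Over these genes SL327 samples lay a median of -0.35 from corn oil in light (SD 0.138, 5 genes called lower) and 0.74 in the dark (30 called higher, 2 lower over all genes), so a difference of the dark groups alone cannot be told apart from a smaller response with 2 samples in each dark group. Over all genes at 30 min, SL327 light against SL327 dark gave 2 up and 7 down, and SL327 against corn oil in the dark groups of the brief light table gave 1 up and 4 down. Exchanged dark and light labels would leave SL327 dark samples above SL327 light ones by about the vehicle rise, and over the 88 genes that rose in vehicle (median 0.588) that excess was 0.0259, with 47 of 88 higher in the dark, which lies between the values the exchange and its absence predict and leaves it open as well. A smaller response under MEK inhibition may also hold.

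Drug interactions that passed were the cycloheximide interaction at 360 min (45 genes) and, over the times tested together, the SL327 interaction with sustained light (48 genes), the SL327 interaction with brief light (1 gene, Btg2) and the U0126 interaction with brief activity in total RNA enhancers (1 region, of Egr3).

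Samples far from the rest of their group were sought in 169 groups, and 41 were found, each the highest of its group. Their chance rate is unknown, as values were untransformed and a library was tested for several features. Among library depths, vehicle brief 360 min replicate 3 held 2293326 reads (others at most 1611058). U0126 unstimulated replicate 2.1 held 6939 over enhancers in total RNA (4266). In the enhancer capture vehicle unstimulated replicate 1.1 held 943575 (393568) and U0126 sustained 20 min replicate 1 held 1073939 (311930). In the gene capture, unstimulated replicate 5 stood high for Fos (0.648, others at most 0.150), Nr4a1 (0.309) and Bdnf (0.148). The shallow brief 60 min replicate 2 stood high for Fos (5.47, others at most 2.25), Nptx2 (0.517) and Bdnf (0.148), and replicate 3 for Arc (0.511). Sustained 60 min replicate 4 stood high for Nr4a1 (5.23), Bdnf (0.158) and Pcsk1 (0.913). Single high values were Bdnf in sustained 360 min replicate 1 (2.68), and Pcsk1 in unstimulated replicate 3 (0.144) and brief 360 min replicate 3 (0.186).

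In the enhancer capture the shallow U0126 brief 60 min replicate 1 stood high for Fos regions at chr12:86776490-86777950 (113), chr12:86795730-86797290 (153) and chr12:86826280-86829680 (59.1), and for Nr4a1 regions at chr15:101076090-101077720 (47.9) and chr15:101140860-101142350 (83.0). Replicate 2 stood high in U0126 at 20 min of sustained activity for the first 2 of these Fos regions (5.10 and 16.5), for Fos at chr12:86818760-86820490 (29.4) and for Nr4a1 at chr15:101076090-101077720 (58.7). It did so in U0126 at 20 min of brief activity for Fos at chr12:86812220-86813790 (4.19) and chr12:86818760-86820490 (9.66) and for Arc at chr15:74509120-74510330 (4.88), and in vehicle for Arc unstimulated (0.729) and Fos at chr12:86818760-86820490 after brief 60 min (6.98). At the Fos region chr12:86911680-86913040 replicate 2 stood high in vehicle sustained 60 min (5.30) and brief 60 min (3.46), and in U0126 sustained 20 min (5.45), sustained 60 min (4.94) and brief 20 min (3.35). Replicate 1 stood high for Fos at chr12:86776490-86777950 in U0126 unstimulated cultures (0.397) and for Nr4a1 at chr15:101083840-101085090 in vehicle brief 60 min (2.30). It also did so at chr15:101145990-101147070 in vehicle unstimulated (2.44), vehicle sustained 20 min (9.20) and U0126 sustained 60 min (3.97).

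Other splits of the samples into groups of the same sizes were counted to ask whether chance can be excluded. For sustained activity in the gene capture at 20 min the share was 2 of 100 (real 6, highest other 13). The split with 13 genes set unstimulated replicate 5 with sustained 20 min replicates 5 and 7. The share was 1 of 100 at 60 min (real 36, highest other 27) and at 360 min (real 197, highest other 190). For brief activity it was 1 of 100 at 20 min (real 6, highest other 4) and at 60 min (real 15, highest other 6). For sustained against brief at 60 min it was 2 of 100 (real 21, highest other 28), so that another split called more genes there too. At 360 min it was 1 of 100 (real 187, highest other 161). For captured enhancers it was 1 of 35 at sustained 20 min (real 4), sustained 60 min (real 34) and brief 20 min (real 6). That is the lowest share possible there (highest other 0 each). For the difference between patterns it was 1 of 100 (real 7, highest other 5). Same-number samples mostly varied together in both captures, which the splits ignore, so these shares alone do not exclude chance. Where the real count was 0 every split gives as many, so the splits do not bear on chance, for brief 360 min (100 of 100, highest other 1), brief 60 min in the enhancer capture (35 of 35, highest other 0) and the effect of U0126 on the sustained enhancer response (100 of 100, highest other 1). For U0126 in unstimulated cultures (100 of 100, real 0) a split that set vehicle replicate 5 with U0126 replicates 5 and 7 called 103 genes, and for U0126 and the brief enhancer response (100 of 100, real 0) a split that set replicates 1 and 2 against 3 and 4 at 20 min, and mixed them otherwise in the unstimulated and 60 min groups, called 106 regions. Both point to a structure of the samples apart from the groups, whose source was not tested. For sustained against brief at 20 min (10 of 10, real 0, highest other 0) and for brief light at 30 min (1 of 10, real 3, highest other 0) the splits are too few for a share under 0.05.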

How the results depend on the processing

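Replicates were few and enhancer counts shallow. In simulated data with sustained activity limma recovered 0% of enhancers changed by a log2 of 1 and 20% of those changed by 2 in total RNA, where the median library held 6249 reads, and 0% and 5% in the enhancer capture, so counts of 0 in limma there exclude little. In edgeR on total RNA 90% and 100% were recovered. That simulation held only 134 regions with more reads and used a set dispersion that was not estimated from the data. Its shares therefore cannot be set against those of limma, and do not show that edgeR counts of 0 are well powered. The simulated data held only sustained against unstimulated vehicle cultures, and recovery was not measured for effects of U0126. Where a group keeps 1 replicate, it is assumed to vary like the others. The effect of U0126 on the brief response in the gene capture, with its alternatives, was not run. Visual cortex columns carry no replicate numbers, so no paired analysis was possible there. The cause of the changes below was not tested, except that fewer samples enter the subsets, the first-culture fits and the fits without a replicate.

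Leaving out 1 replicate kept the counts within 1.5 times for sustained activity in the gene capture at 20 min (4 to 6), 60 min (34 to 37) and 360 min (191 to 201). It did so for brief activity at 60 min (13 to 15) and 360 min (0), sustained against brief at 20 min (0), 60 min (19 to 24) and 360 min (167 to 183), and cycloheximide vehicle (194 to 205). The same held for the effects of U0126 on introns and captured enhancers and on the sustained response of enhancers in total RNA (0), for captured enhancers after brief 60 min (0), and for brief light at 150 min (0). Other ranges were, for the gene capture, brief 20 min 3 (without vehicle brief 20 min replicate 7) to 6, the U0126 effect 0 to 1 (without vehicle sustained 360 min replicate 2), and U0126 in unstimulated cultures 0 to 6 (without vehicle unstimulated replicate 5). For cycloheximide they were 9 (without cycloheximide unstimulated replicate 1) to 74 (without vehicle sustained 360 min replicate 2) for the interaction and 19 (without vehicle unstimulated replicate 1 or cycloheximide unstimulated replicate 2) to 25 (without vehicle unstimulated replicate 2) in unstimulated cultures. For introns they were sustained 20 min 13 (without replicate 2 of that group) to 29 (without replicate 1) and sustained 60 min 509 (without unstimulated replicate 2) to 754 (without sustained 60 min replicate 1). Brief 20 min ranged from 7 (without replicate 1) to 14 (without unstimulated replicate 2), brief 60 min 0 to 1 (without unstimulated replicate 2), and sustained against brief 51 to 98. For enhancers in total RNA they were sustained 19 (without unstimulated replicate 2) to 38 (without sustained 20 min replicate 2) and brief 0 (without brief 20 min replicate 1) to 11 (without unstimulated replicate 1). There the U0126 effect on the brief response ranged from 0 (without unstimulated replicate 1) to 1 (without U0126 brief 60 min replicate 1), and sustained against brief 0 (without sustained 60 min replicate 1) to 13 (without brief 20 min replicate 1). For captured enhancers they were sustained 20 min 1 (without unstimulated replicate 1) to 8 (without sustained 20 min replicate 3) and sustained 60 min 5 (without replicate 1) to 38 (without replicate 3). Brief 20 min there ranged from 0 (without unstimulated replicate 1) to 10 (without replicate 3), and sustained against brief 1 (without sustained 60 min replicate 1) to 9 (without brief 20 min replicate 1). In the visual cortex they were sustained light 30 min 25 to 81 (without light replicate 3) and 150 min 7 to 33 (without light replicate 1). The SL327 effect on sustained light ranged from 14 to 67. Brief light at 30 min ranged from 1 (without corn oil dark replicate 1) to 2 (without replicate 2), and the SL327 effect on brief light 0 (without corn oil dark 30 min replicate 2) to 2 (without SL327 dark 30 min replicate 1).

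With the replicate block, introns passed in 201 at sustained 20 min, 4827 at 60 min, 184 at brief 20 min, 51 at brief 60 min and 822 between sustained and brief, and U0126 effects in 4 (sustained) and 2 (brief). For enhancers in total RNA 25 passed after brief activity. Beyond these and the values given beside the results, the block moved no other count of these tables by over 1.5 times and no other call of a list. Elsewhere the labels state a shared dissection only for cultures of 1 group, and the rule that every same-number pair correlate over 0.1 was not met. In the gene capture 149 of 164 same-number pairs correlated over 0.1 and 37 of 47 samples correlated best with their own number, with cycloheximide 6 of 12 and 6 of 8, and in the enhancer capture 161 of 171 and 38 of 39. Most samples with the same number thus varied together in the gene and enhancer capture, which fits without the block leave out. In these experiments the block gave 3 genes for U0126 in unstimulated cultures, 73 for the cycloheximide interaction, and 17, 57, 13 and 20 captured enhancers at sustained 20 min, sustained 60 min, brief 20 min and between them.

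Scaling by the median log ratio over all features sets the median change near 0 by construction, which removes any broad shift. It moved the gene capture to 116 at sustained 360 min, 101 between sustained and brief at 360 min and 111 for cycloheximide vehicle. It gave 20 larger and 12 smaller responses with cycloheximide, introns 811 up and 528 down at sustained 60 min, and U0126 brief 1. Enhancers in total RNA came to 27 up and 8 down after sustained activity and 11 between sustained and brief. Captured enhancers came to 19 at sustained 20 min, 28 up and 6 down at 60 min, 1 at brief 60 min and 22 between. Sustained light came to 21 at 30 min and 15 at 150 min, and the SL327 effect to 16. Median shifts over 0.1 not given elsewhere were 0.10 for brief 60 min, 0.17 for cycloheximide unstimulated, 0.69 for brief and 0.23 for sustained against brief in total RNA enhancers, and -0.51 and -0.59 for U0126 there. For captured enhancers they were 0.59 and 0.31 after brief 20 and 60 min, 0.81 for sustained against brief, and -0.34 and 0.47 for U0126. In the visual cortex it was -0.12 for SL327 and brief light.

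With the pseudocount at the 1st percentile, U0126 in unstimulated cultures gave 1, enhancers in total RNA between sustained and brief 11, and captured enhancers after brief 20 min 3. With no filter, introns gave 8 for U0126 sustained, 12 at brief 60 min and 10 for U0126 brief, and enhancers in total RNA 16 after brief activity and 5 for U0126 brief. With the first culture only, U0126 in unstimulated cultures gave 3, enhancers in total RNA 2 after brief activity and 8 between sustained and brief, and captured enhancers 7 at sustained 20 min and 3 between. In edgeR 16 enhancers in total RNA passed after brief activity and 2 for U0126 brief.

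With the duplicated column kept as vehicle brief 60 min, introns gave 15 at sustained 20 min, 974 at 60 min, 12 at brief 20 min and 0 between sustained and brief, and enhancers in total RNA 24 after sustained activity, 0 for U0126 brief and 0 between. With it kept as U0126 sustained 60 min, introns gave 222 between sustained and brief and enhancers 0 for U0126 brief. With the shallow brief 60 min library left out, U0126 in unstimulated cultures gave 2. Replicates 5 to 7 only gave 8 at brief 60 min and 13 between at 60 min. With the shallow U0126 brief 60 min library left out, captured enhancers gave 19 and 57 at sustained 20 and 60 min, 13 and 1 at brief 20 and 60 min and 23 between. Replicates 1 and 2 only gave 0 and 2 at sustained 20 and 60 min, 0 at brief 20 min and 0 between, and replicates 3 and 4 only 42, 97, 16 (brief 20 min), 1 (brief 60 min) and 56.

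Of named values, 4554 of 5039 kept their side of the threshold without 1 replicate, 525 of 539 with no filter, 515 with the 1st percentile, 484 with scaling, 434 of 463 with the block, 375 of 405 with the first culture only, 148 of 171 in edgeR and 129 of 183 with the duplicated column as vehicle (181 as U0126). The size of the changes was not compared. For captured enhancers 67 of 96 did so in replicates 1 and 2 only (29 weaker), 81 in replicates 3 and 4 only and 86 without the shallow U0126 library. For the gene capture 110 did so in replicates 5 to 7 only (16 weaker) and 123 without the shallow library (2 weaker). Values that turned direction after sustained activity in total RNA were chr5_17281980_17283110 (2.52), chr1_133470000_133471130 (2.44) and chr4:48100770-48101890 of Nr4a3 (2.32) with the first culture only, the last also without vehicle unstimulated replicate 2 (1.64). After brief activity they were chr11:68906450-68909430 of Per1 (-2.0 with the first culture only) and chr10:18509590-18510620 of D10Bwg1379e (0.90 with the duplicated column kept as vehicle brief 60 min).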

Other observations

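Cycloheximide alone changed the panel in unstimulated cultures (n = 2 in each group). Of 283 genes, 26 were higher and 6 lower with the drug, and the 32 fell to 19 without vehicle unstimulated replicate 1 or without cycloheximide unstimulated replicate 2. The largest rises were in Egr1, a zinc finger transcription factor, by a log2 fold change of 5.92 ± 0.51 (adjusted p = 6.9e-06), in Egr2 by 5.85 ± 0.34 (adjusted p = 2.9e-07) and in Fos by 4.98 ± 0.34 (adjusted p = 7.7e-07). Arc, a synaptic regulator, rose by 3.76 ± 0.51 and Junb by 3.37 ± 0.47 (adjusted p = 0.000384 each). Pcdh20, a protocadherin, fell by 2.68 ± 0.41 (adjusted p = 0.000694) and Adcyap1, which encodes the peptide PACAP, by 2.02 ± 0.35 (adjusted p = 0.00224). Npas4 stood at -0.06 ± 0.35 (adjusted p = 0.938) and Bdnf at 0.39 ± 0.35 (adjusted p = 0.549).

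By fry the immediate-early transcription factors moved upward on balance (adjusted p = 0.0024), with 6 of 16 higher over the panel and 7 adjusted over the list alone. So did the cAMP and CREB feedback genes (adjusted p = 0.0179; 3 of 9, 4 alone), the ERK pathway feedback regulators (adjusted p = 0.0214; 4 of 8, 5 alone), the growth arrest regulators (adjusted p = 0.0246; 3 of 7, 5 alone), and the synaptic effectors and late response genes (adjusted p = 0.0278 each; 2 of 11, 3 alone, and 1 of 13, 1 alone). The secreted factors did not pass (adjusted p = 0.333), with 2 higher and 1 lower of 12, and as many over the list alone.

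Comparisons in this part that were chosen only after the result was seen are those of the U0126 table at 360 min. Against vehicle sustained 360 min its libraries differed in 0 genes in limma, with 17 at an unadjusted p below 0.05. By fry the ERK pathway feedback regulators and late response genes lay lower (adjusted p = 0.0157 each, with 0 of 8 and 0 of 12 passing, and 0 adjusted over either list alone). In introns, with the replicate block, fry called the ERK pathway feedback regulators lower with U0126 in unstimulated cultures (adjusted p = 0.00326, and 0.105 without the block), with 0 of 14 passing and 5 adjusted over the list alone. With the block they also passed in U0126 at 20 min of sustained activity (adjusted p = 0.00741, and 0.171 without) and of brief activity (adjusted p = 0.00534, and 0.102 without), and between sustained and brief activity at 60 min (adjusted p = 0.00452, and 0.0615 without). The cAMP and CREB feedback genes passed with the block in U0126 at 20 min of brief activity (adjusted p = 0.0295, and 0.102 without).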
